A study of Mus musculus with 2 samples.

How the data were processed

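Ribosomal-RNA-depleted total RNA of the nucleoplasmic fraction of mouse bone-marrow-derived macrophages was sequenced in 2 libraries of 1 group, labelled as biological replicates 1 and 2, with RNA inputs of 500 ng and 1 µg per the labels. The labels call the fraction both nucleoplasmic and nuclear.

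The authors deposited a gene-level table and 2 transcript-level tables for each library. Per the file headers, all use the mm10 assembly and the GENCODE M21 annotation, and replicates were kept separate. The gene-level table and the alignment-based transcript table were derived from alignments to the transcriptome, and the index-based transcript table was derived from the reads and a transcript index. The names and versions of the aligner and of the quantification tools are not given in the sources used here. The deposited expected counts are estimated read counts that need not be whole, since reads shared by several transcripts are divided among them. TPM, as the authors deposited it, divides counts by effective length and scales them to the same total over all entries of a table. FPKM, also deposited by the authors, is scaled by length and sequencing depth. Very short RNAs have small effective lengths, so that small RNA genes take most of TPM. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes, like near-identical copies, are uncertain.

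Rows that name no gene of the annotation were left out of totals and tests. They were 26248 rows with numeric identifiers (7e-05% and 9e-05% of counts in replicates 1 and 2), 96 spike-in control rows (0.0 counts in the gene-level table) and the phiX174 control (0.144% and 0.0809%). The 55536 genes that remained were classed by their annotated type, and coordinates are those of the GENCODE M21 annotation. Expected counts were rounded to whole numbers. Totals were 20612078 and 22772081 counts in the gene-level table. Limits from a count of 0 use 3 counts, and they and the p-values on counts cover counting error only.

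Library sizes were scaled by TMM (edgeR 4.0.16, R 4.3.3), and the biological coefficient of variation was taken from the edgeR common dispersion with an intercept alone. Since 1 library stood against 1, no model with residual degrees of freedom could be fitted. Each gene's counts were compared between libraries with a two-sided exact binomial test against the TMM library shares, Benjamini-Hochberg adjusted, and a gene passed at an adjusted p under 0.05 with an absolute log2 ratio of at least 1. Ratios used 0.5 added to each count. These adjusted p-values treat counts as the only error. The spread between cultures is left out, so alternatives used an edgeR exact test with the dispersion set in advance to 0.01 or 0.04.

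The 33 gene lists, the contrasts, the tests in the report and most alternatives were fixed before the data were examined. The closing section names the alternatives and the tests of explanations that were chosen later. High levels were those above the 90 percentile of protein-coding genes. A list's level was its median of mean log2(TPM + 0.1), placed among 10000 random lists of the same size and broad class, with members and random genes at 10 or more counts over both libraries. A list's difference between libraries was its median log2 ratio, placed among 10000 random lists matched on mean expression in 20 bins. Both are descriptions. The 7 contrasts between lists were two-sided permutation tests of the difference in mean log2(TPM + 0.1) with 100000 resamples, adjusted over the 7. A fold on this scale understates differences of low genes. Retained-intron shares are percents of transcript TPM in transcripts annotated as retained introns, compared in 2 permutation tests. They cover genes with 100 or more counts in both libraries that have such a transcript in the annotation. Lists share some genes, such as Cd14 and Lyz2, and members found in both lists of a contrast were left out of it.

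Genes were named by a rule fixed beforehand: in each list the 3 members with the highest mean TPM and the 1 with the largest ratio among those at 100 or more counts in both libraries; a fixed set of inflammatory, regulatory and nuclear RNAs; the 10 protein-coding and 10 other genes with the highest TPM; the 5 genes up and 5 down with the largest ratios past the test among those at 100 or more counts in both libraries; and the 10 highest retained-intron shares. Other members of the lists are named as examples chosen after their values were seen, and the groups in the closing observations were too.

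The tests were tried on simulated data. With Poisson counts drawn at the real genes' mean rates, which hold no spread between cultures, the binomial test over 22502 genes called 99.0% of 100 genes changed by 1.5 on the log2 scale, 100.0% of 100 changed by 2.5 and 0.0045% of unchanged genes. The contrast test gave p under 0.05 in 4.0% of 200 null contrasts. Alternatives covered the scaling, count minimums, the pseudocount, FPKM in place of TPM, the index-based table, the test and each replicate left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and DESeq2 1.42.0 were also used.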

Results

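Nuclear RNA was sequenced from bone-marrow-derived macrophages of C57BL/6J mice, primary phagocytes grown from marrow. The cells had met lipid A, the part of bacterial endotoxin that Toll-like receptor 4 (TLR4) senses, before: they received 100 ng/ml for 12 h, were kept without it for 12 h, and were then stimulated again with 100 ng/ml for 50 min. Ribosomal-RNA-depleted total RNA of the nucleoplasmic fraction was measured in 1 group of 2 libraries, labelled as biological replicates 1 and 2. The labels give both the same donor entry and name no separate animals or cultures, so SDs measure only the spread between these libraries or genes, which may be technical. P-values on counts cover counting error only, and those of permutation tests rest on the spread over genes. Replicate 1 started from 500 ng of RNA and replicate 2 from 1 µg, so replicate and RNA input cannot be separated. No unstimulated, singly stimulated or whole-cell library was analysed here. Levels are therefore described within these libraries, and no value below is a response to lipid A.

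The libraries held 20612078 and 22772081 counts in annotated genes, for replicates 1 and 2. A count of 0 allows up to 3 counts, or 0.146 and 0.132 CPM (depth-scaled counts), and this limit covers counting error only. At 10 or more counts in both libraries, 13831 genes were detected, of which 11082 were protein-coding, 2138 were long noncoding RNA (lncRNA) genes, 518 were pseudogenes, 78 were small RNA genes and 15 were encoded in the mitochondrial genome.

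What the nuclear RNA consisted of was the opening question. Shares here are of counts in annotated genes, taken from alignments to the transcriptome. RNA outside annotated transcripts, such as introns that none of them holds, is not covered. Protein-coding genes held 70.5% ± 0.054 of counts (SD, n = 2), lncRNA genes 13.5% ± 0.106, small RNA genes 11.2% ± 0.421, mitochondrially encoded genes 3.49% ± 0.341 and pseudogenes 1.34% ± 0.131. Much of the noncoding share came from abundant nuclear RNAs. Malat1, an lncRNA of nuclear speckles (chromosome 19, 5795690 to 5802672), took 9.45% ± 0.354 of counts. Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb inactive (chromosome 9, 78175303 to 78175633), took 6.45% ± 0.307. Rpph1, the RNA of ribonuclease P, took 1.75% ± 0.462, and Neat1, the scaffold of paraspeckles, took 0.578% ± 0.0013. In TPM (transcript abundance, which divides counts by effective length), small RNA genes took 72.7% ± 1.67 and protein-coding genes 18.7% ± 1.26. TPM of other genes is therefore low in absolute terms and moves with the small RNAs. In the deposited table made from reads and a transcript index, called index-based here, TPM was lower, at a median of 0.671 of the gene-level value in replicate 1 and 0.316 in replicate 2 over 7845 protein-coding genes (Spearman's rho across genes 0.960 and 0.966). The SDs of TPM below do not cover this difference between tables. Among the nuclear lncRNAs, Malat1 stood at 14072 ± 4900 TPM, Neat1 at 639.5 ± 84.2, Xist at 79.7 ± 7.69 and Tug1 at 36.3 ± 2.81. The RNA of RNase MRP, Rmrp, stood at 65289 ± 829 TPM and telomerase RNA, Terc, at 8.2 ± 2.49. An overlapping entry of Rmrp, annotated as lncRNA, stood at 4926 TPM in replicate 1 and 27948 in replicate 2. The level and SD of Rmrp therefore depend on how reads were divided between these entries. Small RNA values from near-identical copies, such as the 7SL RNA genes Rn7s1 and Rn7s2, are uncertain.

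**Figure D1:**
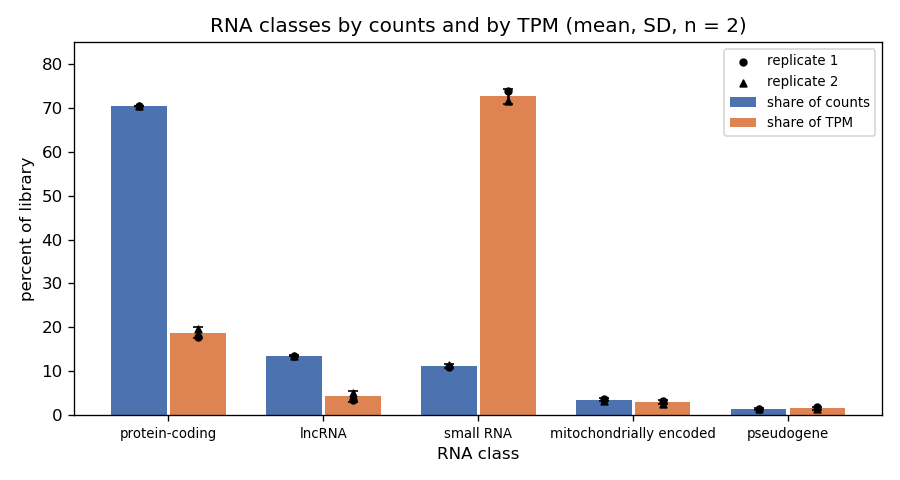
Percent of each library in each RNA class (vertical axis, percent) by counts and by TPM, with bars for the mean, error bars for the SD (n = 2) and a symbol for each replicate. Small RNA genes took 11.2% of counts and 72.7% of TPM.

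Genes of the macrophage lineage were abundant, and markers of other cell types were near 0 apart from a few genes. All 16 macrophage markers lay above the median of the 12140 protein-coding genes with 10 or more counts over both libraries, which was 3.54 TPM, and 11 lay above the 90 percentile, 28.4 TPM. Lyz2 (lysozyme) stood at 1010 ± 30.5 TPM (SD, n = 2), Ctss (cathepsin S) at 695 ± 185, Adgre1 (the F4/80 antigen) at 470 ± 28.7 and Csf1r, the receptor for colony-stimulating factor 1, at 219.6 ± 37.3. Fcgr1, a high-affinity antibody receptor, stood at 82.6 ± 49.4 and was the 1 member that passed the test between libraries. The 52 markers of 10 other cell types had a mean log2(TPM + 0.1) of -2.19, against 6.23 for the macrophage markers. The difference was 8.42, or 343-fold on that scale (two-sided permutation test across genes, 100000 resamples, adjusted p = 3.5e-05 over 7 contrasts, from p = 1e-05, the smallest that the resamples can give). Genes are not independent replicates, and this holds for every such test here. Among the other cell types, all 4 natural killer markers had 0 counts in both libraries. The B cell markers reached at most 0.245 TPM (Cd79b), the neutrophil markers 0.61 (S100a9), the mast cell and basophil markers 0.05 (Ms4a2), the fibroblast markers 0.08 (Col1a2), the erythroid markers 0.315 (Hba-a2) and the dendritic cell markers 0.88 (Ccr7). The exceptions were Cd4 at 15.2 ± 1.27 TPM in the T cell list, Pf4 (platelet factor 4) at 17.9 ± 0.148 in the megakaryocyte list and Kdr, a vascular growth factor receptor, at 9.13 ± 5.69 in the endothelial list. The rest of those 3 lists stayed at or below 0.69 TPM, the value of Pecam1, in the gene-level table. In the index-based table Pecam1 stood at 6.75 and 0.702 TPM in replicates 1 and 2 and Cd3d at 2.88 and 0.616, so these levels depend on the table. Osteoclast markers were at most 4.34 ± 1.61 TPM (Acp5).

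The list of alternative activation genes was low beside the macrophage markers. Its mean log2(TPM + 0.1) was 0.30 against 6.23, a difference of -5.92 (n = 10 and 16 genes, permutation test, adjusted p = 3.5e-05, from p = 1e-05, the smallest possible). Arg1 (arginase 1) had 3 and 6 counts, Retnla 0.035 ± 0.0495 TPM and Chil3 1.35 ± 0.198. Mrc1, the mannose receptor, at 36.7 ± 9.93 and Il4ra, the interleukin 4 receptor chain, at 29.8 ± 6.97 were the 2 members above the 90 percentile of protein-coding genes. None of the 10 passed the test between libraries in the gene-level table, over all genes or adjusted over the list alone, while in the index-based table Arg1 (3 and 12 counts there) passed at a log2 ratio of 2.14 and Cd163 at -1.20.

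**Figure D2:**
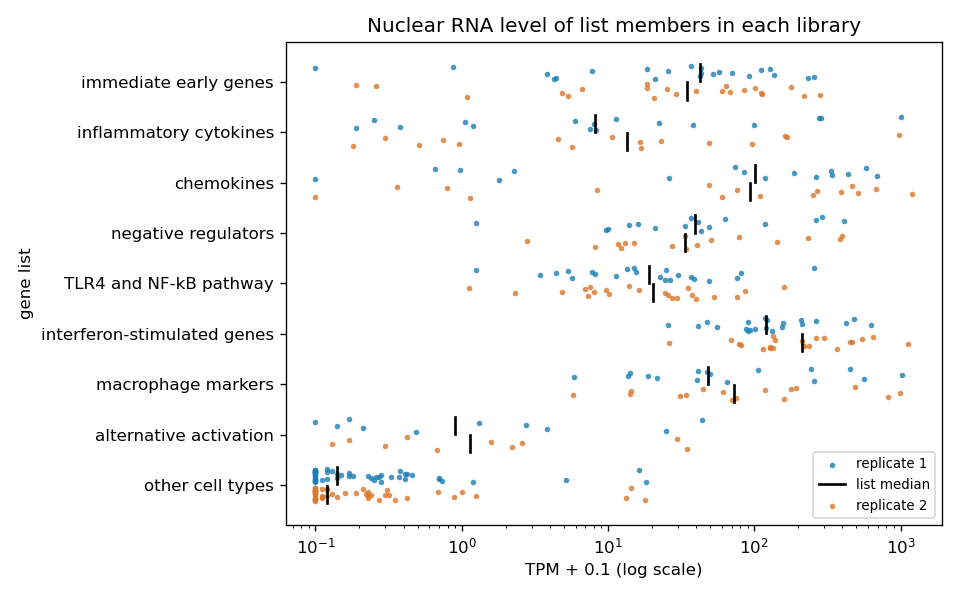
TPM + 0.1 (horizontal axis, log scale) of every member of 8 gene lists and of the 52 markers of other cell types, with a point per gene and library, coloured by replicate, and a black line at each list median. Interferon-stimulated genes had a median of 170 TPM and the alternative activation list 0.918 TPM.

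Interferon-stimulated genes were high throughout the list. Their median was 170 TPM, 20 of 21 lay above the 90 percentile of protein-coding genes, and the lowest, Irf9, stood at 25.8 ± 0.502 TPM. Rsad2 (viperin) reached 876 ± 355 TPM, Ifit2 569 ± 119, Oasl2 438 ± 18.2, Mx1 406 ± 200 and Irf7, a transcription factor of the interferon response, 339 ± 181. The list's mean lay 4.05 above that of the inflammatory cytokines on the log2(TPM + 0.1) scale, or 16.6-fold (7.31 ± 1.20, n = 21, against 3.25 ± 3.69, n = 16, SD over genes, permutation test, adjusted p = 7e-05).

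Inflammatory cytokine RNAs spanned a wide range. Tnf, encoding tumour necrosis factor (chromosome 17, 35199381 to 35202007), stood at 990.4 ± 18.1 TPM, Il1a at 224 ± 86.7, Il1b at 222 ± 76.4 and Csf1 at 97.8 ± 2.18. Il6 was at 10.9 ± 0.481, Il12b at 5.15 ± 0.955, Il23a at 0.8 ± 0.226 and Il12a at 0.175 ± 0.0354. Ifnb1, encoding interferon beta, was at 8.16 TPM in replicate 1 and 16.6 in replicate 2. The list median was 11.5 TPM, with 5 of 16 members above the 90 percentile. Its level lay at the 98.9 percentile of random protein-coding lists of the same size, and at 94.2 in replicate 1 alone.

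Chemokines were higher at the median, 97.4 TPM, with 11 of 16 above the 90 percentile. Ccl5 stood at 945 ± 363 TPM, Cxcl2 at 523 ± 82.1, Cxcl10 at 507 ± 242, Ccl4 at 424 ± 119.95, Ccl3 at 412 ± 33.0 and Cxcl1 at 61.1 ± 17.5, whereas Cxcl9 was at 0.78 ± 0.127 and Ccl17 had 0 counts. The difference from the cytokines, 1.96 on the log2 scale, did not pass the test (n = 16 and 16, permutation test, adjusted p = 0.198).

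Negative regulators of TLR and NF-kB signalling had a median of 36.9 TPM, and 15 of 16 lay above the median protein-coding gene. The highest were Tnfaip3 (the ubiquitin-editing protein A20) at 399.7 ± 18.1, Nfkbia (the inhibitor IkB alpha) at 345 ± 77.6, Nfkbiz at 249 ± 22.1 and Socs3 at 131 ± 17.6. Irak3, a kinase-like inhibitor of the pathway, stood at 15.5 ± 0.75. Their mean lay 1.98 above that of the cytokines, which did not pass the test (n = 16 and 16, permutation test, adjusted p = 0.107). The 22 TLR4 and NF-kB pathway genes had a median of 20.0 TPM, led by the co-receptor Cd14 at 207 ± 66.6, Irak2 at 83.8 ± 3.08 and Nfkb1 at 75.9 ± 0.163, with Tlr4 itself at 14.5 ± 0.785. They lay 1.13 below the negative regulators (4.10 ± 1.72 against 5.23 ± 2.08), again not past the test (n = 22 and 16, permutation test, adjusted p = 0.107).

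Immediate early genes, which are transcribed within minutes of stimulation, had a median of 38.7 TPM, and 12 of 22 lay above the 90 percentile. Zfp36, an RNA-binding protein that shortens the life of cytokine mRNAs, stood at 268 ± 16.03 TPM, Klf6 at 227 ± 9.04, Junb at 153 ± 35.4, Dusp1 at 124 ± 18.2, Egr1 at 106 ± 8.06 and Jun at 53.9 ± 14.9. The difference from the cytokines was 1.30 on the log2 scale (n = 22 and 16, permutation test, adjusted p = 0.226).

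Further lists described the effector state. Among antimicrobial and scavenger genes (median 72.8 TPM), Saa3 stood at 821 ± 155 TPM, Cybb at 279 ± 7.26 and Cd36 at 18.7 ± 6.70. Among inducible enzymes (median 5.62 TPM), Acod1, which makes itaconate, reached 876 ± 63.4, Sod2 204 ± 45.5 and Ptgs2 33.2 ± 4.48, whereas Nos2, the inducible nitric oxide synthase, was at 5.86 ± 3.61. Inflammasome genes had a median of 62.8 TPM with Nlrp3 at 187 ± 17.3, and MHC class II genes 27.5 TPM with Cd74 at 171 ± 21.4. Mir155hg, the host transcript of microRNA 155, stood at 199 ± 25.5 TPM and Mir22hg at 114 ± 4.40, while the other 4 inflammation-linked lncRNAs were at or below 1.01 TPM (Ptgs2os2). Housekeeping genes had a median of 36.4 TPM with Actb at 973 ± 39.9, glycolysis genes 17.2 TPM with Pkm at 84.96 ± 7.91, ribosomal protein genes 25.8 TPM with Rpl41 at 111 ± 9.58, and snoRNA host genes 8.74 TPM with Gas5 at 38.7 ± 2.79. Replication-dependent histone genes had a median of 0.745 TPM, and their near-identical copies make single values uncertain.

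The closeness of the replicates was examined next. Across 15136 genes, log2(TPM + 0.1) correlated with Pearson's r = 0.957 and Spearman's rho = 0.963. The biological coefficient of variation was 0.208 (edgeR common dispersion). The counts differed by more than Poisson noise, with a chi-square of 64.8 per degree of freedom over 13831 genes, so they were not the same counts given under both labels. This does not show separate cultures, since separate library preparations would differ as well.

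Between the 2 libraries, 1007 of 22502 genes passed a binomial test on counts with a ratio of at least 2-fold (Benjamini-Hochberg adjusted), 705 higher and 302 lower in replicate 2. This compares those libraries, not conditions, and has no replicate check. Among the 8641 genes with 100 or more counts in both, 170 passed, 132 higher and 38 lower. Of the 1007, 500 passed in the same direction in the index-based table. There the balance was the other way round, and of the genes differing between the 2 libraries 913 were higher and 1272 lower in replicate 2. If the libraries are allowed to vary beyond counting, with a dispersion of 0.04, an edgeR exact test called 166 genes, 129 of them higher in replicate 2.

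Interferon-stimulated genes were higher in replicate 2. All 21 members had a log2 ratio above 0 with TMM scaling, or 19 with library totals, where Irf9 and Oasl2 fell below 0, and the median was 0.54, at the 100 percentile of 10000 expression-matched random lists. Of these, 3 passed the test, both over all genes and adjusted over the list alone: Cmpk2 was 2.67-fold higher in replicate 2, Isg15 2.24-fold and Irf7 2.20-fold. All 3 passed in the index-based table too. The chemokine list had 2 of 16 past the test over all genes, Cxcl11 at 3.71-fold and Ccl12 at 2.496-fold higher in replicate 2, and 3 adjusted over the list alone. Its median log2 ratio over 15 measured members was -0.03 and its mean 0.24, opposite in sign, and the median was 0.23 in the index-based table. A correction for GC content and transcript length covered only genes with 100 or more counts in both libraries. Over the 12 chemokines left, the corrected median was 0.27. Before correction the middle values of those 12 were -0.03 (Ccl7) and 0.56 (Ccl2), so the shift from -0.03 cannot be ascribed to GC content or length. The cytokine list had 2 of 16 by either adjustment, Il27 at 2.11-fold and Ifnb1 at 2.10-fold higher in replicate 2, with a median log2 ratio of -0.12, or -0.01 in the index-based table with 7 members above 0 and 8 below.

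Among the immediate early genes 3 of 22 passed, over all genes and adjusted over the list alone, and all 3 were higher in replicate 1: Fosb 8.36-fold (83 and 10 counts), Nr4a1 4.26-fold and Fos 2.07-fold. Of the 3, 2 passed in the index-based table, and Fos had a log2 ratio of -0.97. The list's median log2 ratio of -0.09 lay at the 17.9 percentile of matched lists. Of the negative regulators 2 of 16 passed by either adjustment, in opposite directions, and the list's median log2 ratio of -0.08 and mean of 0.01 differed in sign. Il10, encoding the anti-inflammatory interleukin 10, was 2.86-fold higher in replicate 1 (33.4 and 11.6 TPM), and Socs1 was 2.31-fold higher in replicate 2. None of the 22 TLR4 and NF-kB pathway genes passed, over all genes or adjusted over the list alone. Their median log2 ratio was -0.04, or 0.02 in the index-based table with 12 members above 0 and 10 below, and Ly96, with the largest ratio, was at -0.81. Among inducible enzymes 2 of 10 passed over all genes, Nos2 at 2.51-fold and Ch25h at 3.38-fold higher in replicate 2, and 3 adjusted over the list alone. By either adjustment 1 gene passed in each of the antimicrobial list (Lcn2, 2.80-fold higher in replicate 2), the macrophage list (Fcgr1, 2.09-fold), the endothelial list (Kdr, 2.53-fold) and the cell cycle list (Ccna2, 2.08-fold higher in replicate 1, which did not pass in the index-based table). The cell cycle list had a median log2 ratio of -0.68 at the 0.06 percentile of matched lists, with 9 of 10 members below 0, against -0.40 and 7 of 10 in the index-based table. The RNP small RNA list had 2 of 6, Rn7s1 and Rn7s2, and the histone list 12 of 67 by either adjustment, 11 of them higher in replicate 2. The median log2 ratio of the histone list, 0.85 at the 100 percentile with 43 of 49 measured members above 0, exceeded that of the interferon-stimulated genes. After the correction for GC content and transcript length, which left 5 of its members, it was 0.43. Of the 257 small RNA genes tested 74 passed (28.8%, against 4.48% of all genes tested), 73 of them higher in replicate 2. Apart from the ribosomal protein and mitochondrial lists, given next, no member of the remaining lists passed over all genes in the gene-level table, and adjusted over the list alone 1 did, the erythroid gene Hba-a2 with 7 and 0 counts. Over all lists, the members that passed in the index-based table alone were Arg1 and Cd163, Mx1 (log2 ratio 1.02), Cxcl10 (1.06), Cxcl3 (-1.30), Il23a (-1.33), Cd3d (-1.09), Col1a2 (-2.09), Pecam1 (-1.96), Meg3 (-1.09) and 4 histone genes. Ribosomal protein genes had a median log2 ratio of 0.13 at the 99.98 percentile, or 0.056 with library totals and 0.034 after a correction for GC content and transcript length, with 1 of 83 past the test (Rps21), which did not pass in the index-based table. Adjustment over the list alone gave the same number.

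**Figure D3:**
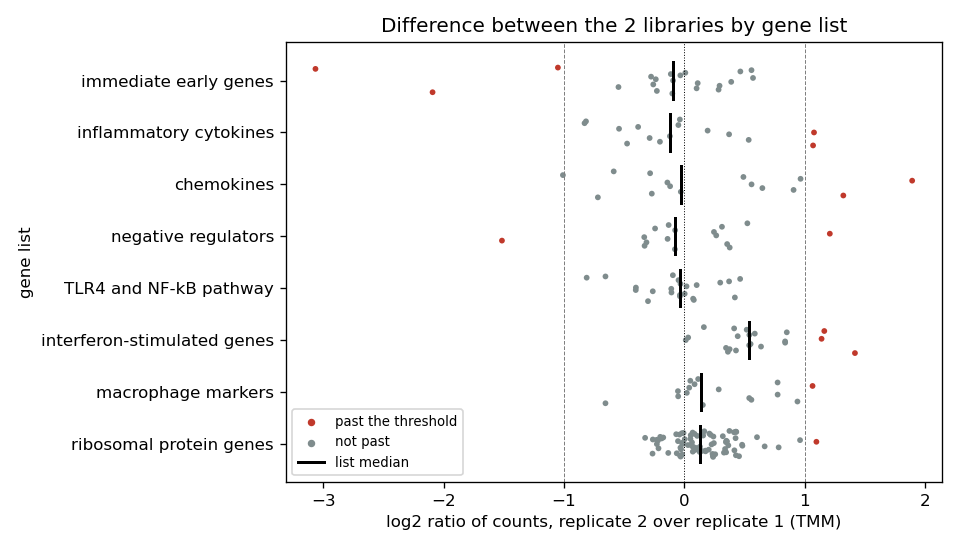
Log2 ratio of counts between the libraries, replicate 2 over replicate 1 after TMM scaling (horizontal axis), for members of 8 lists with 10 or more counts over both libraries, with a point per gene, red where past the test, black lines at list medians and dashed lines at the 2-fold limits. All 21 interferon-stimulated genes lie above 0, with a median of 0.54; with library totals in place of TMM, Irf9 and Oasl2 lie below 0.

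The largest differences among genes with 100 or more counts lay outside the immune lists. The mitochondrial ribosomal RNAs mt-Rnr2 (mitochondrial genome, 1094 to 2675) and mt-Rnr1 (70 to 1024) were 12.2-fold and 6.65-fold higher in replicate 2. The lncRNA-annotated copy of Rmrp (chromosome 4, 43492783 to 43493063), which overlaps the ribozyme gene of that name, was 7.62-fold higher, and its reads cannot be assigned with certainty. Gm26447, a small RNA gene, had 111 and 922 counts. CT010467.1, annotated as ribosomal RNA, had a log2 ratio of 2.81 here and 0.58 in the index-based table. Of the 5 genes highest in replicate 1 by ratio, Gm24497, Gm28438 and Gm10222 had log2 ratios of -3.49, -3.06 and -1.70, which turned to 0.38, 0.31 and 0.31 in the index-based table. Gm28439 was at -2.42 and -1.78 and Gm28048 at -1.79 and -0.65. Within the mitochondrial list, 6 of 15 passed by either adjustment, 5 higher in replicate 2, and 3 of the 6 passed in the index-based table. Those 3 were mt-Rnr1 and mt-Rnr2, higher in replicate 2, and mt-Nd2, lower. No protein-coding mitochondrial transcript was thus called higher in both tables. The most counted, mt-Co1, had a log2 ratio of 0.04.

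Whether RNAs of inducible genes carried more annotated retained introns was asked with the transcript tables. Per gene, the median share of TPM in transcripts annotated as retained introns was 21.5% over 5196 genes, and 600 genes exceeded 50%. The 5196 were those with such a transcript among the 8641 genes with 100 or more counts in both libraries. By share of counts the median was 11.3% and 476 genes exceeded 50%, and in the index-based table the median was 27.5% with 849 genes. Immediate early, cytokine and chemokine genes averaged 30.5% ± 16.1 (SD over 12 genes), with Dusp1 at 58.2% and Cxcl2 at 43.4%. Members without a retained-intron transcript, such as Tnf, Fos and Jun, were not measured. The TLR4 and NF-kB pathway genes averaged 28.8% ± 20.0 (16 genes), with Nfkb1 at 75.4%. These differed by 1.71 percentage points (permutation test, adjusted p = 0.812). Housekeeping and glycolysis genes averaged 15.8% ± 18.0 (16 genes), with Actb at 9.57%. That difference of 14.7 points had p = 0.0333 and did not pass after adjustment over 2 contrasts (permutation test, adjusted p = 0.0665). It passed in the index-based table, with a minimum of 10 counts and with shares of counts. The highest shares, from 96.0% to 100%, were those of Slc27a1, Daam2, H2-Q10, Gm37423, Gm43305, Spaca6, Tmem132a, Plxnb3, Lilrb4a and Ldhd. H2-Q10 and Lilrb4a have near-identical relatives and are uncertain. The share rests on the annotation of transcripts and does not measure unspliced RNA over unannotated introns. Over annotated ones, reads of RNA not yet spliced can count toward it. It therefore cannot tell retained introns from unspliced RNA.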

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

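Of the tests in this part, the GC content and transcript length test was set out before its result was seen. The tests on ribosomal protein genes, RNA input, mitochondrial transcripts and nuclear ribosomal RNA were chosen after the values they rest on had been seen. No biological explanation was tested for the patterns in this part, since the design holds 1 group and gives none. A hypothesis on the stage of the response is among the other observations, with its test.

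Some signals lay outside the gene measurements and were singled out because they exceed the 3 counts that a count of 0 allows, as no control libraries were analysed. The phiX174 sequencing control held 29656 counts in replicate 1 and 18440 in replicate 2. Entries with numeric identifiers held 15 counts in replicate 1 and 20 in replicate 2. In the index-based table, spike-in controls held 29.0 counts in replicate 1 and 20.0 in replicate 2, against 0.0 in the gene-level table.

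Interferon-stimulated genes were higher in replicate 2, with a median log2 ratio of 0.54. After subtracting the median of bins by GC content and by transcript length, the median was 0.594 at the 100 percentile of matched lists, which argues against those trends as the cause. More cytoplasmic RNA in replicate 2 would also raise the stable mRNAs of ribosomal proteins, whose median log2 ratio was 0.1277 (95% bootstrap interval 0.066 to 0.218, 80 genes) at the 99.98 percentile of matched lists, but 0.056 with library totals and 0.034 at the 91.8 percentile after the correction for GC content and transcript length. The mainly cytoplasmic 7SL RNAs Rn7s1 and Rn7s2 were 2.39-fold and 2.32-fold higher in replicate 2, but their copies are uncertain and the snRNA gene Gm22513 was 2.40-fold higher as well, so they do not decide it, and without a cytoplasmic library the size needed is not known, so it stays open. RNA input or culture stays open as well: there was 1 library per RNA input amount, so the input, the culture and the library cannot be told apart.

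Mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were higher in replicate 2 by log2 ratios of 2.73 and 3.61. More mitochondrial RNA in general would raise the 13 protein-coding mitochondrial transcripts as well, but their median log2 ratio was -0.312 (95% bootstrap interval -0.631 to 0.553), with 6 above 0 and 7 below. In the index-based table the mitochondrial list of 15, which includes mt-Rnr1 and mt-Rnr2, had a median of -0.457, with 5 above 0 and 10 below. Unequal depletion of ribosomal RNA might raise nuclear ribosomal RNA too. The summed counts of nuclear genes annotated as ribosomal RNA had log2 ratios of 2.81 in the gene-level table and 0.5871 in the index-based table, so the tables do not decide it, and the gene-level value rests on CT010467.1 with 1481 and 10904 counts.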

How the results depend on the processing

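The list contrasts kept their direction and side of the threshold under all 49 alternative values. The main results that did not are given here, the rest as counts, and the cause was not tested unless said. Chosen after seeing the data were the index-based table for class shares, correlation, genes differing, list ratios and single genes, the GC and length correction, coding genes alone and TPM rescaled without small and mitochondrial RNA. Differences between the libraries need both, so no replicate could be left out there. Genes detected were 8641 at 100 counts, a stricter filter. By TPM, RNA class shares were 4.20% lncRNA, 2.87% mitochondrially encoded, 18.7% protein-coding, 1.496% pseudogene and 72.7% small RNA. Of counts without small and mitochondrial RNA in the total, RNA class shares: lncRNA were 15.8%, RNA class shares: protein-coding 82.65% and RNA class shares: pseudogene 1.57%, by construction. Of counts in the index-based table they were 14.04%, 65.9% and 5.01%, and RNA class shares: small RNA 11.8%. The replicate correlation was 0.969 with a pseudocount of 1, 0.952 unfiltered, 0.973 at 100 counts in both, 0.971 for CPM and 0.974 in the index-based table; shifts over 0.005 count as moves. The biological coefficient of variation was 0.236 unfiltered and 0.239 with DESeq2. The genes differing between the 2 libraries numbered 5843 with no minimum ratio, 671 among genes with 10 counts in both (648 shared with the 1007), 166 with an edgeR dispersion of 0.04, 2185 in the index-based table (913 higher in replicate 2 and 1272 lower, 502 shared) and 107 among coding genes at 100 counts. The cytokine level percentile ran from 94.2 to 99.9 with a replicate left out, and that of alternative activation from 27.0 to 35.8, with 21.01 in the index-based table. The ribosomal protein median log2 ratio was 0.056 with library totals and 0.034 after GC and length correction, outside its bootstrap interval. Over all lists, 27 alternative level percentiles moved and 180 did not, and 21 alternative median log2 ratios moved and 121 did not. Medians near 0 also changed sign in the index-based table, such as those of the mitochondrial list (0.04 to -0.46) and the snoRNA host genes (-0.08 to 0.10). Of the alternative values for named genes, 128 of 152 TPM values moved by over 1 SD of the replicates in the index-based table, where Tnf was at 532.8 and 255.0 TPM against 1003 and 977.6, and 411 of the log2 ratios kept their direction and side of the test, 10 no longer passed, 5 newly passed and 30 changed sign. With DESeq2 size factors these were Cybb (0.0093), Malat1 (0.011) and Rpl10 (0.0079), and with library totals Oasl2 (-0.041), Siglech (-0.013), Pecam1 (-0.0029), Neat1 (-0.0048), mt-Co1 (-0.030) and Ldhd (-0.048). In the index-based table they were Gm24497 (0.38), Gm28438 (0.31) and Gm10222 (0.31), which had passed in the gene-level table, Pecam1 (-1.96), which passed in the index-based table alone, and, past the test in neither, Tnf (0.10), Nfkb1 (0.070), Lyz2 (0.031), H2-Aa (0.11), Ms4a1 (0.060), Zbtb46 (0.30), Siglech (-0.048), Pf4 (-0.016), Gp9 (1.16), Oscar (1.89), Malat1 (0.064), Snhg1 (0.12), Ldha (0.052), Rpl41 (0.13), Il6 (0.12), Ccl3 (0.19) and Tmem132a (0.023). Of these, Gm28438 and Gm10222 held at most 1.4e-05 TPM in either library of the index-based table. Their sign there came from the 0.5 added to each count and the scaling, so it shows no change of direction. Depth limits genes below 10 counts, where a ratio rests on few reads.

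For the retained-intron share: inflammatory and immediate early minus housekeeping and glycolysis, the difference passed at 14.6 points in the index-based table (adjusted p = 0.0317), 16.1 at 10 counts (adjusted p = 0.0129) and 19.4 by counts (adjusted p = 0.0356), and not with a replicate left out (adjusted p = 0.0856 and 0.0642, all permutation tests). For the retained-intron share: inflammatory and immediate early minus TLR4 and NF-kB pathway, it turned to -0.21 in the index-based table, with adjusted p from 0.222 to 0.976 over the alternatives (permutation tests).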

Other observations

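The gene groups in the next 2 paragraphs were chosen after their values were seen and come from no fixed list. Toll-like receptors besides Tlr4 were present at varied levels: Tlr1 at 147 ± 9.56 TPM (SD, n = 2), Tlr2 at 75.4 ± 0.467, Tlr7 at 57.2 ± 6.10 and Tlr13 at 34.9 ± 0.912, with Tlr5 at 0.145 ± 0.0212. Tlr9, the sensor of unmethylated DNA, was 2.62-fold higher in replicate 2 (1643 and 4522 counts), Tlr11 was 5.97-fold higher (5 and 34 counts) and Tlr2 had a log2 ratio of -0.03. The cathepsin RNAs chosen ran from Ctsl at 68.4 ± 17.2 TPM to Ctsb at 1217 ± 267 and Ctsd at 1251 ± 235. Ctsk, which comes from the osteoclast marker list, stood at 0.715 ± 0.247. All those chosen but Ctsc (log2 ratio -0.12) had ratios above 0, from 0.11 (Ctsh) to 0.60 (Ctsa), and none passed the test. Class I antigen presentation genes had higher ratios in replicate 2 in 7 of 7 genes, with H2-K1 at 0.54, H2-D1 at 0.48, Tap1 at 0.73 and Psmb8 at 1.28 on the log2 scale, of which Psmb8 passed the test. Of 9 genes with redox functions, 3 passed the test, all lower in replicate 2: Cat (catalase) had a log2 ratio of -1.17, Srxn1 of -1.13 and Slc7a11 of -1.06. In the index-based table Cat at -0.998 and Slc7a11 at -0.93 did not reach 2-fold. Hmox1 was at 0.00 and Nqo1, with 4 and 8 counts, at 0.85.

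Mki67, encoding the proliferation antigen Ki-67, had 13328 and 11778 counts, against 409 and 266 for Top2a and at most 56 for the other 8 cell cycle genes. The cell cycle list as a whole had a median of 0.555 TPM, or 0.685 in replicate 1 and 0.345 in replicate 2. Xist, which coats the inactive X chromosome, had 41519 and 49815 counts, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 in both libraries. The labels give the sex as not collected. Lars2 was 3.15-fold higher in replicate 2, with a log2 ratio of 4.12 in the index-based table.

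A hypothesis chosen after the values were seen was that replicate 2 was further along the response, which would lower immediate early genes as interferon-stimulated genes stood higher. The immediate early genes had a median log2 ratio of -0.09434 at the 17.85 percentile of matched lists, with 12 of 21 measured members below 0 and 9 above (13 and 8 with library totals, and 11 and 10 in the index-based table, where the median was -0.06). After the correction for GC content and transcript length the median was -0.08 at the 3.92 percentile, with 14 of 19 below 0, so as a set they may or may not be lower, and the hypothesis stays open. Fos, Fosb and Nr4a1 were higher in replicate 1, but they were picked for that and do not test it.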
